A study of Mus musculus with 6 samples.

How the data were processed

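RNA sequencing libraries of the mouse myoblast line C2C12 were compared between cells with forced expression of Msx1 (n = 3) and control cells (n = 3). Per the labels' protocols, RNA was isolated with Trizol and libraries were made with a NEBNext Ultra kit for Illumina sequencing. The kit name does not mark a strand-specific protocol, and no source used here says that the assignment of reads used strand. Selection of polyadenylated RNA or removal of ribosomal RNA is not given in the sources used here. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

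The authors deposited 1 table of FPKM (fragments mapped to a transcript, scaled by its length in kilobases and by the number of mapped fragments in the library) with 1 column per sample and 1 row per RefSeq transcript. Per the submitters' processing notes, Trimmomatic, HISAT2 and StringTie were used with the mouse build GRCm38 (mm10), and versions and settings are not given in the sources used here. The control columns carry a heading that names a vector and a number from 1 to 3. They were matched by that number to the 3 control samples, whose titles use another word for the control, and the Msx1 columns were matched by name and number. StringTie divides reads among overlapping transcripts by estimation, so FPKM of single transcripts carry that uncertainty, as do genes with near-identical copies, overlapping genes and antisense partners. FPKM are relative to each library's total, so a group-wide shift in a few abundant transcripts moves all others.

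The table held 38468 transcripts, of which 32961 were messenger RNAs and 5507 non-coding RNAs by accession type. Gene symbols for 38193 transcripts came from a RefSeq gene table of the same build and for 156 more from GENCODE. The 119 transcripts without a symbol were kept under their own identifiers and held from 0.246% to 0.884% of the FPKM of a library. FPKM were summed per symbol to 24809 genes, 7069 of which had more than 1 transcript. All 10627 transcripts listed at 0 in every library stayed in the sums. Coordinates are those of the annotation of GRCm38, counted from 1.

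Depth was estimated because no read numbers were used here. In FPKM made from whole fragments, a low value multiplied by transcript length is a multiple of what 1 fragment is worth. The best step gave 22.7, 18.5 and 23.8 M fragments (M, mega) for control replicates 1, 2 and 3. It gave 22.1, 22.9 and 21.0 M for Msx1 replicates 1, 2 and 3. The step was searched only within a preset window, which bounds the depths it can give. From 39.3% to 43.3% of low values lay within 0.1 of a whole multiple, against 20% for a step unrelated to the values. The step was fitted to part of these values, so 20% is not its chance level. Whole reads were not recovered, and these depths are rough estimates. At this depth 1 FPKM on a transcript of 1 kb stands for about 18.5 to 23.8 fragments.

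The test was limma (version 3.58.1, R 4.3.3) on log2(FPKM + 1) with an intensity trend in the prior variance and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Genes were tested where the mean over all 6 libraries was at least 0.5 FPKM, which kept 12371 genes and left out 12438. Changes are given on the log2(FPKM + 1) scale, which understates the change of low genes, and SE is the moderated standard error of limma. Folds are ratios of group mean FPKM without a pseudocount. For Msx1 an exact two-sided permutation test was added, whose smallest possible p with 3 against 3 libraries is 0.1.

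The design, 30 gene lists, the rule for named genes and all alternatives except a length and GC correction were fixed before the data were examined. Of 1023 list entries 1008 were found in the table. The 15 entries of the list of mitochondrially encoded transcripts had no match, so that list is not analysed here and 29 lists were tested. For each list, members called higher and lower over all genes tested were counted, and again adjusted over the list alone. Each list was set against the other genes with camera at a preset correlation of 0.01, adjusted over the 29 lists, and again with camera at an estimated correlation. The latter rests on the few residual degrees of freedom of 6 libraries and has little power. A call lost there does not show that a list was unchanged. The fry test was a further alternative. It asks whether a list's members move one way on balance and does not set them against the other genes.

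Named genes followed a rule. Msx1, Msx2, Myod1, Myf5, Myog, Myf6, Pax7 and Runx1 were always named. The 8 largest increases and 8 largest decreases were named among genes with a mean of at least 5 FPKM in the higher group, no overlap between groups and a symbol that is not a predicted gene, RIKEN clone or pseudogene. Up to 3 members with the smallest adjusted p were named from each list that passed the set test and from the 4 muscle lists, and 1 from every other list. Some genes that the rule names are not reported here. Ranks 9 to 20 in each direction were kept for the closing section. Further list members are given as examples of a count and were chosen after their values were seen.

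The procedure was tested on simulated data for the same comparison, with 12371 genes of which 200 were changed by known folds. It recovered 71.6% of 67 genes changed by 1.5-fold, 85.1% of 67 changed by 2-fold and 98.5% of 66 changed by 4-fold. It called 12 of 12171 unchanged genes. The simulated noise was independent between genes, with random directions and no shift between libraries. In the real data 54.4% of genes were called and calls moved with scaling, so these rates need not carry over. Alternatives covered the pseudocount, the filter, scaling between libraries, limma's options, a block for replicate number, leaving out each replicate, transcripts kept separate, stricter thresholds and other set tests. A correction for transcript length and GC content, chosen after seeing the data, removed the trend of each library with both by natural splines of 4 degrees of freedom. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.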

Results

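Transcript levels were measured by RNA sequencing in C2C12 cells, a mouse myoblast line that stops dividing and fuses into myotubes when serum is withdrawn. Control cells (n = 3) were compared with cells overexpressing Msx1 (n = 3), a homeobox transcription factor of undifferentiated mesenchyme that is known to hold back myogenic differentiation. The comparison addresses which transcripts differ in C2C12 cells with raised Msx1. The labels do not say whether the cells were proliferating or differentiating at harvest, or how dense they were. A difference between the groups in stage or density therefore cannot be told apart from an effect of Msx1, also for the muscle genes. Values are FPKM summed per gene, as mean ± SD, and changes are log2(FPKM + 1) differences, Msx1 overexpression minus control, with adjusted p from limma. Estimated depth lay between 18.5 and 23.8 M fragments (M, mega) per library. Genes at 1 FPKM or more numbered 11459 ± 29.1 in control and 11505 ± 16.3 in Msx1 libraries (n = 3 each). Total FPKM was 425939 ± 16089 in control and 394557 ± 6294 in Msx1 libraries (n = 3 each).

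Msx1 (chromosome 5, 37820491 to 37824585, GRCm38) was at 7.55 ± 0.431 FPKM in control and 953 ± 46.6 FPKM in Msx1 cells (n = 3 each), 126-fold higher. These values cannot separate introduced Msx1 RNA from that of the locus itself. The skeletal actin gene Acta1 (log2 change 2.32, SE 0.11), the Wnt ligand gene Wnt4 (4.25, SE 0.06) and the Wnt feedback gene Axin2 (3.63, SE 0.06) rose, while the early myogenic regulator Myf5 fell by 1.92 (SE 0.07) on the log2 scale. All 35 tested genes of mitosis and 32 of 36 of DNA replication fell. The neutrophil chemokine genes Cxcl5 and Cxcl1 and the collagen crosslinking enzyme gene Lox each fell by more than 3 on the log2 scale.

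The Msx1 libraries read 1004, 943.7 and 912 FPKM for Msx1 against 7.99, 7.13 and 7.54 FPKM in control (log2 change 6.80, SE 0.06, adjusted p = 1.02e-09). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Msx1os, annotated on the opposite strand inside Msx1, went from 0.582 ± 0.099 to 14.3 ± 2.79 FPKM (log2 change 3.26), and reads of the pair cannot be told apart without strand. Msx2, the paralog of Msx1, had a mean of 0.28 FPKM over the 6 libraries and was below the minimum for testing.

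Of 12371 genes tested, 6732 (54.4%) changed, 2718 higher and 4014 lower. A change of at least 1 on the log2 scale was reached by 516 higher and 415 lower genes, and one of at least 2 by 155 higher and 46 lower genes. Groups did not overlap for 7707 genes (62.3%), against 10% by chance. The higher share of the calls, 40.4% with FPKM as deposited, was 51.2% after median-of-ratios scaling (3317 higher, 3161 lower), 45.8% after quantile normalization (3073 higher, 3633 lower) and 55.4% with equal totals without Msx1 (3494 higher, 2814 lower). The first principal component, which separated the groups, held 85.8% of the variance. Correlations of log2 values across genes were 0.9899 to 0.9946 within groups and 0.938 to 0.942 between groups.

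**Figure D1:**
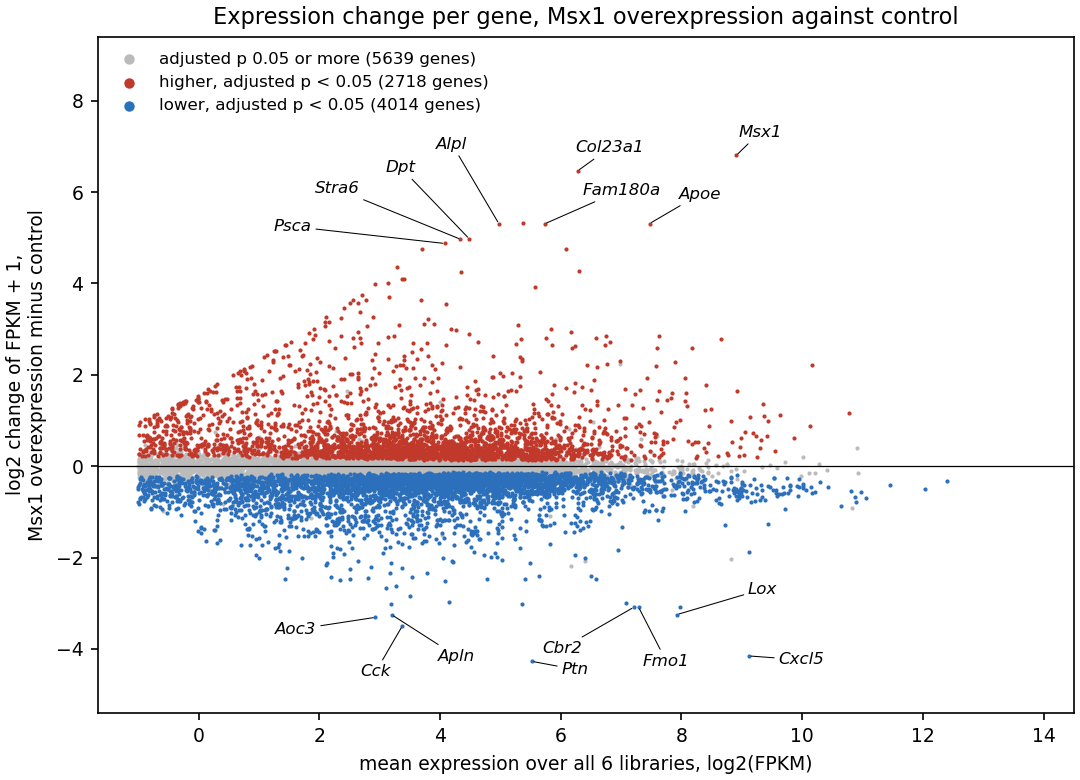
Log2 change of FPKM + 1 (Msx1 overexpression minus control, vertical axis) against log2 of the mean FPKM over 6 libraries (horizontal axis) for 12371 genes, 1 point per gene, with 2718 higher, 4014 lower and 5639 not called. The 16 genes named by the rule on largest changes carry their symbols, and Msx1 lies highest at 6.80.

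The largest increase after Msx1 was in Col23a1, a transmembrane collagen, which rose from 0.768 ± 0.141 to 155 ± 3.77 FPKM (n = 3 each; log2 change 6.47, SE 0.07, adjusted p = 1.87e-09). Apoe, which carries lipids in lipoprotein particles, rose from 8.41 ± 4.52 to 347 ± 11.3 FPKM, and its control libraries were uneven at 5.08, 13.6 and 6.60 FPKM. Alpl, the alkaline phosphatase of mineralizing tissue, rose from 0.609 ± 0.246 to 62.3 ± 2.14 FPKM (log2 change 5.31, SE 0.11). Fam180a rose from 1.70 ± 0.533 to 105 ± 9.22 FPKM, and Dpt, encoding the matrix protein dermatopontin, from 0.436 ± 0.088 to 44.3 ± 3.00 FPKM. Stra6, the receptor for retinol-binding protein, rose from 0.314 ± 0.019 to 40.1 ± 1.25 FPKM, and Psca from 0.189 ± 0.208 to 33.6 ± 1.84 FPKM. Their adjusted p lay between 1.87e-09 and 2.28e-06.

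The largest decreases included Ptn, the heparin-binding growth factor pleiotrophin, which fell from 88.5 ± 5.57 to 3.62 ± 0.167 FPKM (n = 3 each; log2 change -4.27, SE 0.06, adjusted p = 7.62e-09). Cxcl5 fell from 1057 ± 128 to 58.2 ± 4.91 FPKM (log2 change -4.16, SE 0.10). Lox fell from 441 ± 42.6 to 45.5 ± 3.21 FPKM (log2 change -3.25, SE 0.08). The peptide hormone genes Cck and Apln fell from 19.9 ± 1.72 to 0.844 ± 0.14 and from 17.5 ± 0.472 to 0.938 ± 0.143 FPKM. Aoc3, a membrane amine oxidase, fell from 14.6 ± 1.202 to 0.575 ± 0.019 FPKM. The oxidoreductase genes Cbr2 and Fmo1 fell from 265 ± 13.9 to 30.3 ± 2.56 and from 281 ± 25.1 to 32.1 ± 1.55 FPKM. Adjusted p for these genes lay between 7.62e-09 and 7.86e-08.

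**Figure D2:**
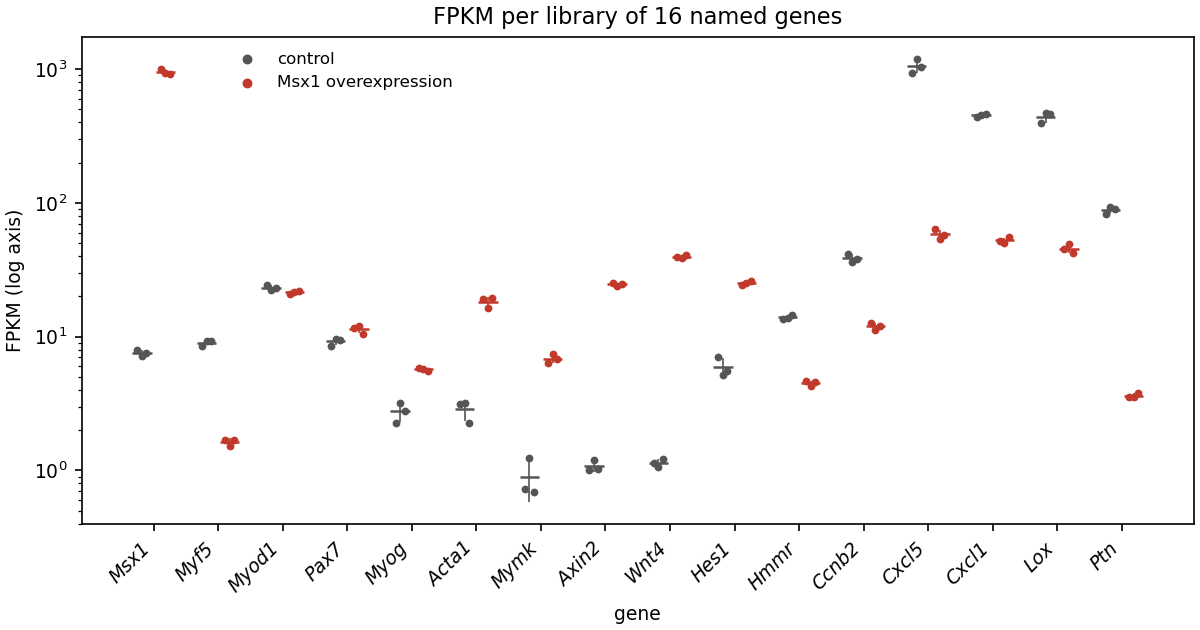
FPKM per library on a log axis for 16 named genes (horizontal axis), with control in grey and Msx1 overexpression in red, each point 1 library, the horizontal bar the mean and the vertical bar the SD of 3 libraries. Groups do not overlap for any of the 16 genes shown, and Myod1, at 23.3 against 21.4 FPKM, is not called.

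Among 17 tested myogenic transcription factors, 7 rose, 4 fell and 6 were not called (7 and 4 adjusted over the list alone). Myf5 fell from 9.01 ± 0.396 to 1.64 ± 0.097 FPKM (n = 3 each; log2 change -1.92, SE 0.07, adjusted p = 2.77e-07). Myog, needed for terminal differentiation, rose from 2.76 ± 0.469 to 5.75 ± 0.153 FPKM (log2 change 0.85, SE 0.10, adjusted p = 1.71e-04), and Klf5 from 7.54 ± 0.30 to 16.4 ± 0.544 FPKM. Myod1, the myogenic determination gene, was at 23.3 ± 0.924 and 21.4 ± 0.677 FPKM and did not pass (log2 change -0.11, adjusted p = 0.109), although it passed with sample weights (adjusted p = 0.0159) and after the length and GC correction (0.0102) in a range of 0.0102 to 0.952 over 19 refits. Pax7, a satellite cell marker, rose from 9.21 ± 0.573 to 11.4 ± 0.751 FPKM (log2 change 0.28, adjusted p = 0.0114), a call lost after the length and GC correction (log2 change 0.08, adjusted p = 0.305; range 9.24e-04 to 0.305 over 19 refits). Myf6 had a mean of 0.095 FPKM over the 6 libraries and was below the minimum for testing. The list as a whole did not differ from other genes (camera adjusted p = 0.572), and its median (-0.01) and mean (-0.06) were below 0 while camera put it above the other genes, and the median was above 0 under each of the 3 scalings (0.03 to 0.10).

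Of 23 tested genes of the contractile apparatus, 14 rose, 5 fell and 4 were not called (14 and 5 adjusted over the list alone). Skeletal alpha-actin Acta1 rose from 2.87 ± 0.516 to 18.2 ± 1.62 FPKM (n = 3 each; log2 change 2.32, SE 0.11, adjusted p = 1.54e-06), cardiac troponin T Tnnt2 from 11.6 ± 1.67 to 47.4 ± 2.63 FPKM, and slow myosin Myh7 from 0.042 ± 0.032 to 1.95 ± 0.093 FPKM. The Z-disc gene Ldb3 (log2 change -1.47) and the tropomyosin gene Tpm2 (-0.76) fell. The list's camera adjusted p was 0.00118, and adjusted p = 0.333 with an estimated correlation. In the list of excitation, calcium handling and energy supply, 12 of 19 rose, 5 fell and 2 were not called (13 and 5 adjusted over the list alone), with adjusted p = 0.0117 and adjusted p = 0.265 with an estimated correlation. Myoglobin Mb rose from 0.168 ± 0.059 to 6.60 ± 1.11 FPKM, cardiac calsequestrin Casq2 from 0.459 ± 0.119 to 2.22 ± 0.149 FPKM and the calcium channel subunit gene Cacng1 from 18.8 ± 0.596 to 28.9 ± 1.67 FPKM, while Musk, which organizes the neuromuscular junction, fell by 0.70 on the log2 scale.

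Of 22 tested genes of myoblast adhesion and fusion, 9 rose, 3 fell and 10 were not called (9 and 3 adjusted over the list alone), with 14 higher and 2 lower after median-of-ratios scaling, 13 and 1 with equal totals without Msx1, and 12 and 5 with sample weights. The fusion gene Mymk rose from 0.888 ± 0.307 to 6.85 ± 0.483 FPKM (n = 3 each; log2 change 2.07, SE 0.12, adjusted p = 3.67e-06) and integrin alpha-3 Itga3 from 70.7 ± 2.70 to 129 ± 2.55 FPKM, while N-cadherin Cdh2 fell from 43.1 ± 1.76 to 22.3 ± 1.21 FPKM. Camera gave adjusted p = 0.0145 for the fusion list, and adjusted p = 0.46 with an estimated correlation. Its median of 0.15 lay within the range of 95% of random lists matched on expression, transcript length and GC content (-0.17 to 0.18).

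Of 31 Wnt signalling genes tested, 20 rose, 6 fell and 5 were not called (20 and 6 adjusted over the list alone). Camera put the list above the other genes with adjusted p = 3.22e-05, and adjusted p = 0.152 with an estimated correlation. Wnt4 rose from 1.14 ± 0.083 to 39.6 ± 1.01 FPKM (n = 3 each; log2 change 4.25, SE 0.06, adjusted p = 6.49e-09). The Wnt target genes Axin2 and Lgr5 rose from 1.07 ± 0.106 to 24.6 ± 0.65 and from 0.173 ± 0.074 to 5.10 ± 0.074 FPKM. The secreted Wnt modulators Sfrp2 (log2 change -1.87) and Dkk2 (-1.50) fell. Of 16 Notch pathway genes 12 rose, 0 fell and 4 were not called (12 and 0 adjusted over the list alone), with adjusted p = 1.09e-04 and adjusted p = 0.152 with an estimated correlation. The Notch target Hes1 rose from 5.89 ± 0.978 to 25.2 ± 0.682 FPKM, the receptor Notch1 from 7.35 ± 0.23 to 14.1 ± 0.636 FPKM and the ligand Dll1 from 1.58 ± 0.195 to 3.71 ± 0.224 FPKM. Under the 3 scalings 11 to 14 Notch genes were higher and 0 lower, after the length and GC correction 8 were higher and 1 lower, with sample weights 13 were higher and 1 lower, and without a filter 14 of 23 were higher and 2 lower.

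Of 24 TGF-beta genes 14 rose, 7 fell and 3 were not called (16 and 7 adjusted over the list alone; 16 higher and 4 lower with equal totals without Msx1). The latent TGF-beta binding protein genes Ltbp2 and Ltbp1 rose from 75.8 ± 2.24 to 243 ± 13.5 and from 45.6 ± 2.09 to 118 ± 4.76 FPKM (n = 3 each), and the signal transducer Smad3 from 19.1 ± 1.29 to 37.9 ± 0.661 FPKM. The target Cnn1 (log2 change -1.52) fell, and camera gave adjusted p = 0.00615, with adjusted p = 0.35 with an estimated correlation. In the FGF, hedgehog and IGF list 15 of 30 rose, 7 fell and 8 were not called (16 and 7 adjusted over the list alone), with adjusted p = 0.00706 and adjusted p = 0.333 with an estimated correlation. The IGF binding protein genes Igfbp2, Igfbp3 and Igfbp5 rose from 101 ± 4.06 to 709 ± 36.2, from 29.0 ± 0.551 to 197 ± 7.71 and from 29.8 ± 3.89 to 142 ± 5.65 FPKM, while Fgf10 fell by 1.72 on the log2 scale.

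Mitosis genes fell throughout, with 35 of 35 tested called lower (35 adjusted over the list alone) and 30 of them by at least 1 on the log2 scale. The spindle gene Hmmr fell from 13.99 ± 0.562 to 4.50 ± 0.185 FPKM (n = 3 each; log2 change -1.45, SE 0.06, adjusted p = 7.42e-07), cyclin Ccnb2 from 38.5 ± 2.84 to 12 ± 0.761 FPKM and the kinetochore gene Nuf2 from 17.4 ± 0.486 to 5.58 ± 0.492 FPKM. Of 36 genes of DNA replication 0 rose, 32 fell and 4 were not called (33 lower adjusted over the list alone). The helicase subunit Mcm4 fell from 22.1 ± 0.722 to 11.2 ± 0.391 FPKM and the checkpoint gene Clspn from 5.196 ± 0.121 to 2.03 ± 0.023 FPKM. Uhrf1, a maintenance factor of DNA methylation, fell from 23.1 ± 3.21 to 8.88 ± 0.275 FPKM (log2 change -1.28). With transcripts kept separate, its most abundant transcript had a log2 change of -0.89 and lost the call (adjusted p = 0.141, range 1.25e-07 to 0.141 over 19 refits). Camera gave adjusted p = 1.71e-15 for mitosis and 4.56e-09 for replication, and adjusted p = 0.265 and adjusted p = 0.333 with an estimated correlation. All 35 mitosis genes were lower under each of the 3 scalings, and 30 or 31 replication genes were. Of 28 cell cycle inhibitors and p53 targets 5 rose, 15 fell and 8 were not called (5 and 16 adjusted over the list alone; camera adjusted p = 0.0983). In that list Gadd45a rose from 20.4 ± 2.04 to 131 ± 4.60 FPKM.

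Inflammatory cytokine and chemokine genes were mostly lower, with 17 of 25 tested called lower, 7 higher and 1 not called (17 and 7 adjusted over the list alone). Cxcl1 fell from 453 ± 11.2 to 52.7 ± 2.34 FPKM (n = 3 each; log2 change -3.08, SE 0.05, adjusted p = 1.21e-08) and the iron-siderophore carrier Lcn2 from 15.5 ± 2.31 to 1.58 ± 0.205 FPKM, while complement C3 (log2 change 2.66) rose. The list's camera adjusted p was 0.0434, and adjusted p = 0.46 with an estimated correlation. It was 0.062 without control replicate 1, 0.0524 without Msx1 replicate 2 and 0.106 with sample weights, in a range of 0.0136 to 0.106 over 18 refits.

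Of 31 genes of cholesterol and fatty acid synthesis 22 fell, 3 rose and 6 were not called (22 and 3 adjusted over the list alone). The desaturase gene Scd1 fell from 125 ± 10.4 to 49.8 ± 1.40 FPKM (n = 3 each; log2 change -1.31, SE 0.07, adjusted p = 2.12e-06) and the sterol carrier Stard4 from 9.66 ± 0.858 to 3.90 ± 0.268 FPKM. Camera gave adjusted p = 6.52e-04, and adjusted p = 0.52 with an estimated correlation. Among 11 adipocyte markers, 1 of which is shared with another list, 7 fell, 1 rose and 3 were not called (8 and 1 adjusted over the list alone), and 2 were higher without control replicate 1. Pparg, the master regulator of fat cells, fell from 4.40 ± 0.362 to 1.32 ± 0.042 FPKM, and Klf15 rose from 1.70 ± 0.109 to 6.09 ± 0.579 FPKM. Camera gave the adipocyte markers adjusted p = 0.0479, and adjusted p = 0.333 with an estimated correlation. The call was lost in 7 of 18 refits (range 0.0178 to 0.151), among them the one without control replicate 1 (0.124).

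Transcripts of ribosomal proteins and of nuclear-encoded oxidative phosphorylation were lower by smaller amounts. Of 55 ribosomal protein genes 50 fell, 0 rose and 5 were not called (52 lower adjusted over the list alone), with a median change of -0.51 (-0.32 after quantile normalization). Rpsa fell from 1109 ± 152 to 576 ± 23.1 FPKM (n = 3 each; log2 change -0.93, SE 0.11, adjusted p = 1.68e-04), Rps23 from 833 ± 98.6 to 498 ± 19.6 FPKM and Rps2 from 67.2 ± 10.3 to 34.1 ± 0.876 FPKM. Rps27, at 11.1 FPKM in Msx1 replicate 1 and at 476 and 488 FPKM in replicates 2 and 3, was among the 5 not called. Values of these genes are uncertain where processed pseudogenes share their reads. Per library, the median deviation of the list was 0.45, 0.11 and 0.23 in control replicates 1, 2 and 3 and -0.26, -0.28 and -0.22 in Msx1 replicates 1, 2 and 3, and 50 members were lower without control replicate 1. The most abundant transcript without a gene symbol stood at 3714, 2061 and 1426 FPKM in the control and at 1663, 1209 and 818 FPKM in the Msx1 libraries, also highest in control replicate 1. Of 41 oxidative phosphorylation genes 32 fell, 0 rose and 9 were not called (33 lower adjusted over the list alone), and 1 was higher with equal totals without Msx1, with sample weights, after the length and GC correction and without control replicate 1. The complex I and IV genes Ndufs4, Ndufa4 and Cox7b fell from 21.4 ± 0.655 to 13.5 ± 0.386, from 375 ± 33.7 to 218 ± 12.9 and from 111 ± 6.33 to 78.0 ± 1.81 FPKM. Camera gave adjusted p = 5.68e-08 and 1.21e-05 for the ribosomal and oxidative phosphorylation lists, and adjusted p = 0.52 with an estimated correlation for both.

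**Figure D3:**
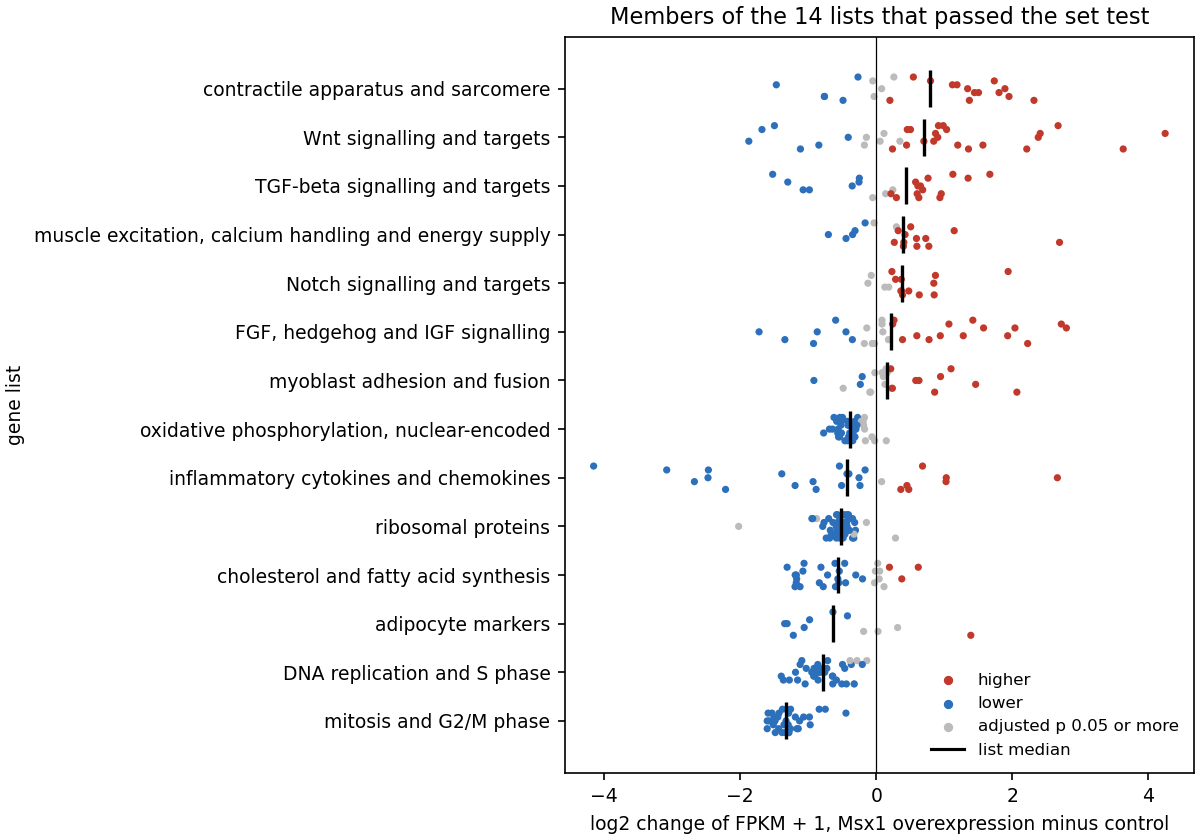
Log2 change of FPKM + 1 (Msx1 overexpression minus control, horizontal axis) of each tested member of the 14 gene lists that passed the set test (vertical axis), 1 point per gene, red for higher, blue for lower, grey for not called, with a black bar at the list median. All 35 mitosis genes lie below 0, and 0 of the 14 lists pass with an estimated correlation.

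Matrix and bone-related lists held strong changes in both directions and did not pass the set test. Of 44 extracellular matrix genes 19 rose, 16 fell and 9 were not called (19 and 16 adjusted over the list alone; camera adjusted p = 0.0565). The elastic fibre gene Fbln5 rose from 25.6 ± 0.323 to 190.4 ± 4.97 FPKM (n = 3 each). That list passed in 5 of 18 refits, among them those without control replicate 2 (0.0202) and without Msx1 replicate 3 (0.04), in a range of 0.0202 to 0.328. Of 20 BMP genes 8 rose, 5 fell and 7 were not called (8 and 5 adjusted over the list alone; adjusted p = 0.11). Bmp7 was listed at 0 in all control libraries and at 18.6, 19.5 and 20.7 FPKM in Msx1 libraries, and the BMP antagonist Grem1 fell by 3.00 on the log2 scale while Nog rose by 3.57. Of 12 osteoblast and chondrocyte markers 7, including Alpl, rose, 2 fell and 3 were not called (7 and 3 adjusted over the list alone; adjusted p = 0.109), and bone regulator Runx2 had a log2 change of 0.29 and the cartilage regulator Sox9 of 0.03, not called. Runx1 was at 23.0 ± 2.89 and 27.2 ± 2.20 FPKM and did not pass (log2 change 0.24, adjusted p = 0.0685). It passed in 8 of 19 refits, among them those without control replicate 2 (0.0122) and without Msx1 replicate 3 (0.0462), in a range of 0.00211 to 0.272. The low end was its most abundant transcript alone, tested with transcripts kept separate (log2 change 0.75), and in that fit another of its transcripts fell (log2 change -1.63, adjusted p = 0.00218).

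Markers of cell types other than myoblasts moved in both directions. Of 17 fibroblast and mural cell markers 7, including Dpt and Pdgfrb (log2 change 1.58), rose, 8, including Pdgfra (-0.999), fell and 2 were not called (7 and 8 adjusted over the list alone; camera adjusted p = 0.116), and 5 were lower without Msx1 replicate 1 or 2. Of 9 neural markers 1 rose, 6 fell and 2 were not called (1 and 6 adjusted over the list alone; adjusted p = 0.064), with Stmn2, a neuronal microtubule gene, falling from 27.0 ± 1.47 to 5.91 ± 0.556 FPKM (n = 3 each). Only 4 epithelial, endothelial and blood cell markers were expressed enough to test, of which Lyz2, the lysozyme of macrophages, rose from 10.3 ± 0.985 to 22.3 ± 2.22 FPKM and 3 fell (1 and 3 adjusted over the list alone; adjusted p = 0.329).

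Homeobox genes other than Msx1 showed 8 of 30 higher, 9 lower and 13 not called (8 and 9 adjusted over the list alone; camera adjusted p = 0.833), with Dlx3 rising from 2.71 ± 0.137 to 10.1 ± 0.344 FPKM and Prrx1 falling by 1.94 on the log2 scale. Of 41 chromatin regulators and reported Msx1 partners 9 rose, 9 fell and 23 were not called (9 and 9 adjusted over the list alone; adjusted p = 0.488), and 15 rose after median-of-ratios scaling. In it the Polycomb gene Cbx7 rose from 6.37 ± 0.394 to 16.5 ± 0.643 FPKM (n = 3 each). Of 34 SRF, YAP and immediate early genes 9 rose, 21 fell and 4 were not called (9 and 21 adjusted over the list alone; adjusted p = 0.0906), and the growth-factor-induced gene Egr1 fell from 153 ± 25.5 to 27.7 ± 0.072 FPKM. That list passed in 4 of 18 refits, among them the one without control replicate 3 (0.0276), in a range of 0.0276 to 0.26.

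The hypoxia and glycolysis list had 10 of 35 higher, 14 lower and 11 not called (10 and 14 adjusted over the list alone; camera adjusted p = 0.954), with the hypoxia-induced gene Ndrg1 rising from 68.4 ± 0.84 to 316 ± 14.4 FPKM (n = 3 each) and the glycolytic gene Pgk1 falling by 0.80 on the log2 scale. Of 32 genes of the unfolded protein and amino acid stress response 8 rose, 12 fell and 12 were not called (9 and 13 adjusted over the list alone; adjusted p = 0.925), with 7 lower without Msx1 replicate 1. In it the stress-induced pseudokinase Trib3 rose from 2.09 ± 0.566 to 10.4 ± 0.407 FPKM. Of 30 interferon-stimulated genes 8 rose, 7 fell and 15 were not called (8 and 7 adjusted over the list alone; adjusted p = 0.812), with Ifit3, a near copy of Ifit3b, rising from 4.18 ± 0.192 to 8.74 ± 0.069 FPKM. Of 28 replication-dependent histone genes 10 rose, 9 fell and 9 were not called (10 and 10 adjusted over the list alone; adjusted p = 0.879), with 6 higher without control replicate 2 and 5 without Msx1 replicate 3. H2ac8, one of many near-identical histone copies, fell from 1.82 ± 0.124 to 0.67 ± 0.104 FPKM. For these 4 lists and the homeobox list camera pointed up while the median was below 0, and of their means only that of the unfolded protein list (0.0082) was above 0. The chromatin list had a median of -0.0024 and a mean of 0.03. Each of these 6 medians was above 0 under at least 1 of the 3 scalings.

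In all, 14 of 29 lists passed with camera at the preset correlation, 7 higher and 7 lower. Of the 29, 0 passed with an estimated correlation and 22 passed by fry. Because fry does not set a list against other genes, of which 54.4% were called, its passes do not single out these lists. Estimated correlations were below the preset 0.01 for the Notch (-0.0298), adipocyte (-0.0187), excitation (-0.0163) and Wnt (-4e-04) lists. A higher correlation between members therefore cannot be what ended those calls. With an estimated correlation camera has few residual degrees of freedom here, so lost calls cannot be read as an effect of correlated members alone. The ribosomal and oxidative phosphorylation lists had estimates of 0.758 and 0.7249. FPKM as deposited are relative to each library's total, so calls of small changes depend on scaling, as the splits of higher and lower calls show.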

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

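Among alternatives, only the length and GC correction was chosen after the data were seen. Most of 95 named genes were picked for large changes or small p in these data, which favours stability. Of the 95, 91 kept direction and side of the threshold in every refit that tested them. Myod1, Pax7 and Runx1, named before the data were seen, and Uhrf1 did not. Myh7, Casq2 and H2ac8 were not tested at a mean of at least 2 FPKM. With a log2 change of at least 1 required, 931 genes changed, 516 higher and 415 lower, because the threshold is stricter, and at adjusted p under 0.01 it was 4876. Leaving out 1 library at a time gave 5586 to 7095 changed genes, 2284 to 2823 higher and 3280 to 4272 lower. Sample weights gave 8770 and transcripts kept separate 5733. Deviations from the group means correlated at 0.055, 0.226 and 0.037 between samples of the same replicate number, 1 to 3. Between unlike numbers they correlated from -0.204 to 0.133, and control replicate 1 correlated best with Msx1 replicate 3. With 3 libraries per group this cannot tell whether replicate numbers pair the samples. With replicate number as a block, 6747 genes changed (2692 higher, 4055 lower), Runx1 passed (adjusted p = 0.0411), the adipocyte list did not (0.0571), and no other call on a named gene or list changed. All reversed directions were in lists that did not pass, and their cause was not tested. For glycolysis and hypoxia, camera's adjusted p in the other direction was 0.966 without a filter, 0.952 with median-of-ratios scaling, 0.829 with equal totals, 0.866 with sample weights, 0.772 with transcripts kept separate and 0.995 after the length and GC correction. With 1 library left out it ran from 0.835 to 0.994 in either direction, reversed only without control replicate 2 (0.862) or Msx1 replicate 3 (0.994). For histones the p in the other direction was 0.411 without a filter, 0.886 with median-of-ratios scaling, 0.874 with quantile normalization, 0.723 with equal totals and 0.305 by fry. With 1 library left out it ran from 0.616 to 0.994 in either direction, reversed only without control replicate 2 (0.9215) or Msx1 replicate 3 (0.994). For the unfolded protein list the p in the other direction was 0.978 with transcripts kept separate and 0.628 by fry, and with 1 library left out p ran from 0.726 to 0.994 in either direction, reversed only without control replicate 2 (0.9875). Reversals elsewhere were the myogenic transcription factors by fry (0.0832), interferon genes at a mean of at least 2 FPKM (0.991) and by fry (0.979), and without a filter the homeobox list (0.967) and the epithelial, endothelial and blood cell markers (0.821). Camera with an estimated correlation ended the call of all 14 lists that passed (adjusted p from 0.152 to 0.52). Over the 18 refits with the preset correlation, the inflammatory and adipocyte lists lost the call in 3 and 7, and the other 12 in 0. Of those that did not, the BMP list passed in 1, the p53 list in 2 and the neural, SRF and matrix lists in 4, 4 and 5 of 18 refits, and the 8 histones with a mean of at least 2 FPKM passed as higher (0.0283). Other counts within lists moved by over 1.5 times as follows. Without a filter 26 contractile, 3 adipocyte, 4 neural, 5 epithelial, endothelial and blood and 6 histone genes were higher, and 8 BMP, 5 bone and 15 histone genes lower. At a mean of at least 2 FPKM 5 interferon, 3 bone and 6 histone genes were higher, and 3 BMP, 1 bone and 0 histone genes lower. With sample weights 2 adipocyte and 16 chromatin genes were higher, and 7 myogenic, 12 interferon and 14 chromatin genes lower. With transcripts kept separate 5 interferon and 5 histone genes were higher, and 2 excitation and 4 interferon genes lower. With equal totals 14 chromatin and 5 cholesterol genes were higher and 5 homeobox genes lower, and after quantile normalization 5 fibroblast and mural markers were lower. The contractile list's median, 0.80, was 0.12 without a filter and 1.26 with a pseudocount of 0.1. Other medians of passing lists moved by over 1.5 times without a filter (excitation 0.21, Wnt 0.44, FGF, hedgehog and IGF 0.13, inflammatory -0.23, adipocyte -0.21), after the length and GC correction (fusion 0.09, FGF, hedgehog and IGF 0.09), with equal totals (fusion 0.26) and after quantile normalization (ribosomal -0.32). Depth was estimated only, so no interval for counting error is given.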

Other observations

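The comparison of Runx1 start sites, the count of neighbouring pairs with unlike names and the length and GC correction were tests chosen only after results were seen. Tests of neighbouring pairs, matched random lists, gaps between groups, splits of libraries and transcript shares were not in the fixed design either.

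Ranks 9 to 20 of the increases included Enpp2, the enzyme autotaxin that makes lysophosphatidic acid, which rose from 3.98 ± 1.01 to 132 ± 5.24 FPKM (n = 3 each; limma log2 change 4.76, SE 0.13, adjusted p = 9.11e-08). The matrix proteoglycan gene Dcn rose from 5.07 ± 1.35 to 89.7 ± 5.51 FPKM and Clec3b, encoding tetranectin, from 7.12 ± 2.59 to 151 ± 9.91 FPKM. Serpina6, the corticosteroid-binding globulin, rose from 0.281 ± 0.197 to 20.9 ± 1.11 FPKM, Rnase1 from 0.131 ± 0.116 to 17.4 ± 3.03 FPKM, Cxcl15 from 0.418 ± 0.081 to 17.5 ± 0.923 FPKM, Cdcp3 from 0.041 ± 0.028 to 13.0 ± 0.493 FPKM and the apolipoprotein gene Apoc4 from 0.312 ± 0.541 to 20.4 ± 2.96 FPKM. Chil1 was listed at 0, 0 and 0.025 FPKM in control and at 15.6, 13.9 and 15.7 FPKM in Msx1 libraries, and Bpifb5 at 0 in all control and at 24.9, 27.2 and 26.3 FPKM in Msx1 libraries.

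Ranks 9 to 20 of the decreases held the proteoglycan versican Vcan, from 32.5 ± 5.27 to 3.21 ± 0.252 FPKM (n = 3 each; limma log2 change -2.98, SE 0.12, adjusted p = 5.25e-07), and the BMP antagonist Grem1, from 242 ± 22.7 to 29.2 ± 1.66 FPKM. The copper-binding ferroxidase Cp fell from 73.7 ± 16.6 to 8.11 ± 0.577 FPKM, the cytokine Il6 from 5.30 ± 0.915 to 0.128 ± 0.075 FPKM and the antimicrobial peptide gene Camp from 10.4 ± 1.32 to 1.05 ± 0.293 FPKM. The glutamate transporter Slc1a3 fell from 72.7 ± 8.54 to 12.2 ± 0.221 FPKM and the natriuretic peptide clearance receptor Npr3 from 9.28 ± 1.04 to 0.834 ± 0.188 FPKM. Ranbp3l, Rasl11a and Rnf150 fell by 3.02, 2.83 and 2.5 on the log2 scale.

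Runx1 changed in its start sites more than in its total. Transcripts from the distal start (chromosome 16, 92826149, GRCm38) went from 7.70 ± 1.95 to 1.92 ± 0.256 FPKM and those from the proximal starts (92696125 and 92697328) from 15.3 ± 1.12 to 25.3 ± 2.23 FPKM (n = 3 each). The distal share was 33.2% ± 4.25 and 7.08% ± 1.11, with an exact permutation p of 0.1, the smallest possible, and the gap between the groups, 22.2 points, was wider than the widest range within a group, 7.89 points. Of 3734 genes with at least 2 transcripts, a mean of at least 5 FPKM and a value above 0 in every library, 85 had a transcript whose share shifted by 20 points or more with no overlap between the groups, against at most 54 in the other 9 splits. Runx1's largest shift of a single transcript was 24.8 points, and 2.79% of the genes had a larger one, whether or not the groups overlapped.

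Lower mitosis transcripts were weighed against technical explanations. After the length and GC correction the list median was -1.30 against -1.33 before, so a trend with length and GC does not account for it. The gap between the lowest control and the highest Msx1 library was 1.18, against ranges of 0.0913 within control and 0.1449 within Msx1 libraries. The spread among these libraries therefore does not account for it either. Replicates may share a culture, so differences between cultures cannot be excluded. Effects of Msx1 on division and a difference in culture density or stage at harvest stay open and were not tested. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes, the real one with 6732, and the highest of the others gave 2, but 10 splits are too few for a share under 0.05.

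Lower ribosomal protein transcripts were weighed in the same way. The length and GC correction left the median at -0.41 against -0.51, and of the 3 scalings the one nearest 0 left -0.32, which argues against either as the whole cause. The gap between the groups, 0.328, was smaller than the range among control libraries, 0.348, so differences between libraries within a group may contribute, although that range rests on control replicate 1 (0.45 against 0.11 and 0.23) and 50 of 55 members were lower without it. Random lists matched on expression, transcript length and GC content had a median of -0.28 (95% of lists from -0.40 to -0.20). For oxidative phosphorylation it was -0.24 (-0.35 to -0.12) against -0.39. A part of both changes could therefore be shared with other genes of like expression, length and GC content. Only a list's own members were kept out of its draws, so genes of the other list or of related function could be among them. A biological effect of Msx1 on these genes stays open and untested.

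Genes higher by at least 2 on the log2 scale lay next to each other more often than chance placement gives. The 155 such genes made 13 neighbouring pairs among tested genes, against a mean of 1.93 and a maximum of 9 in 10000 random sets (permutation p = 1e-04, the smallest possible), with Apoc4, Apoc1 and Apoe on chromosome 7, Igfbp2 and Igfbp5 on chromosome 1 and Mymk and Adamtsl2 on chromosome 2 among them. Only 1 pair, Msx1 and Msx1os, overlapped or lay within 1 kb, which argues against overlapping gene models for the other pairs. That pair, the overexpressed gene and its antisense partner, is among the 13. Apoc1 and Apoe lay 3584 bp apart, Igfbp2 and Igfbp5 5590, Mymk and Adamtsl2 7174, and Apoc4 and Apoc1 8019. The limit of 1 kb cannot exclude read-through over such distances. The remaining pairs lay further apart, up to 338307 bp for Atp1b1 and Dpt. Neighbours were defined among tested genes only, so untested genes may lie between them. The 7 pairs whose symbols do not share their first 3 letters still exceeded the mean of 1.86 (maximum 11, permutation p = 0.0031), so tandem copies of related genes do not account for all. No biological explanation was tested, and the 46 genes lower by at least 2 on that scale made 2 pairs (mean 0.174, permutation p = 0.011).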
